A study of Homo sapiens with 35 samples.

How the data were processed

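RNA from the hepatocyte fraction of 35 cultures was sequenced by the authors as stranded mRNA libraries on an Illumina NovaSeq, on the same lane. Per the labels, reads were trimmed with Trim Galore 0.6.4, aligned to GRCh38 with STAR 2.6.1d and counted per gene with featureCounts 1.6.4; the annotation release and the strand setting are not stated. The unit of the deposited table is the read count per gene, with no normalization. The table held here ended after 4196 complete gene entries, and 1 incomplete entry was left out. Of these genes 4087 (97.4%) were found in GENCODE release 29, all on chromosome 1, and genes on other chromosomes and mitochondrial transcripts were not analysed here. CPM is therefore the count of a gene scaled to the total of the tested genes after TMM scaling, and not to all reads of a library.

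Libraries were grouped by culture, drug and LPS into 12 groups. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 1821 of the 3182 genes with any count. A single fit over all 35 libraries with one mean per group was made with edgeR 4.0.16 (TMM, quasi-likelihood F test, two-sided) in R 4.3.3, with 23 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. SE is the size of the log2 fold change divided by the square root of F. By chance 91.1 genes would have an unadjusted p under 0.05 if the p-values were calibrated. LPS with vehicle, and levofloxacin against vehicle, gave from 3 to 16 such genes, and from 10 to 47 with the replicate number in the fit. The p-values may thus be too large there, and 0 called genes does not show that an effect is absent. The p-values measure only the spread between these libraries, since the labels do not say whether replicates are separate cultures.

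The replicate number was checked as a pairing. Profiles of the same number in other groups correlated with a median r of 0.597 (0.197 to 0.903, n = 187 pairs), and those of different numbers with a median of -0.299 (n = 374). Blocked values are therefore given beside the numbers of genes called and for some genes. A gene's SE and adjusted p that are not marked as blocked do not account for this pairing. The biological coefficient of variation was 0.475, and 0.215 with the block. For libraries whose left-out partner leaves 1 library in a group, that library is assumed to vary as the other groups do.

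Before the data were examined, 41 gene lists were fixed. Of their 827 distinct genes 70 were tested, and 12 lists had the 3 tested members required. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and fry was run as a further test.

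Named genes were chosen by a rule fixed in advance. In main comparisons it took the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, and 3 and 3 in other comparisons. At most 4 members of a list were added. Clone, LINC and antisense names were passed over. Which of these genes are given with full statistics was decided after their values were seen. Results of some genes that the rule took are not reported here.

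Alternatives were DESeq2 1.42.0 (its size factors and its Wald test), no filter on low counts, the replicate block, a fit on the groups compared only and leaving out each library. Leaving out a whole replicate number, averages over vehicle and levofloxacin, and leave-outs with the block were chosen after seeing the data. Size factors shifted the median log2 fold change of a comparison by between -0.0267 and 0.0219. The tests were also tested on simulated data with planted changes. The simulated counts took the additive replicate shifts and the gene spreads of the blocked fit. Each planted change was equal in all replicates, so the shares called may be too high for the real data. In the simulated data 0 of 99 random lists were called. Those lists held random unchanged genes whose counts were drawn independently. They do not show how often camera calls a list of genes that vary together. Tables and figures were made with Python 3.11.15.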

Results

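RNA was measured in hepatocytes differentiated from the IMR90 induced pluripotent stem cell line and kept alone (monoculture) or with Kupffer cells, the macrophages of the liver, made from the same line (co-culture). Cells were treated for 48 h with vehicle (0.2% DMSO), 25 µM trovafloxacin or 25 µM levofloxacin, each with or without 100 ng/ml lipopolysaccharide (LPS), a bacterial product that activates macrophages. Hepatocytes were collected as the cells that did not bind beads against CD163, a Kupffer cell surface protein. The 12 groups held 3 libraries each (replicates 1, 3 and 4), except trovafloxacin with LPS in monoculture, which held 2 (replicates 1 and 4), for 35 libraries in all. Of the genes in the count table used here 3182 had any count, and those that could be placed lay on chromosome 1, between positions 11869 and 185628527 (GRCh38), so every statement concerns that part of the genome. The counts in this table summed to between 1975348 and 5794906 per library (median 3919506), which is not the depth of the libraries. Of these genes, 1821 were tested, and n is 3 libraries per group unless stated. CD163, ALB and PANX1 were not analysed here.

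The first comparison asked how co-culture altered the transcripts of the hepatocyte fraction in vehicle without LPS. Macrophage transcripts were higher in co-culture: C1QA (ENSG00000173372.17, chromosome 1, 22636506 to 22639608), a subunit of complement C1q, stood at a log2 fold change of 5.90 ± 1.90 (SE; edgeR adjusted p = 0.523), higher in 3 of 3 pairs of equal replicate number, and, with the replicate number as a block, at 5.88 ± 1.15 (adjusted p = 0.00433). CTSS, a lysosomal protease, stood at 4.43 ± 1.32 (adjusted p = 0.502; 4.62 ± 0.88 and 0.00433 with the block), and FCER1G, an Fc receptor chain, at 4.48 ± 1.32 (adjusted p = 0.502; 4.52 ± 0.87 and 0.00433 with the block). All 8 tested macrophage markers had a positive log2 fold change, 0 passed over all genes and 7 when adjusted over the list alone. The list stood higher in co-culture (camera adjusted p = 3.39e-08, and 0.423 with an estimated correlation), and it did not pass by fry. The mean CPM of the 8 markers ran from 82.4 to 2790 over the 18 co-culture libraries and from 2.78 to 82.7 over the 17 monoculture libraries.

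Over all 1821 genes the edgeR quasi-likelihood test called 0 genes for co-culture, with 78 at an unadjusted p under 0.05, and DESeq2 called 21 (20 higher, 1 lower). With the replicate block edgeR called 48 genes, 36 higher and 12 lower. That number fell to 5 without the monoculture vehicle library of replicate 1, to 22 without that of replicate 4, and to 24 and 23 without the co-culture vehicle libraries of replicates 1 and 4. Among the blocked calls were TNFRSF14, a receptor of the TNF receptor family (log2 fold change 6.31 ± 0.88, adjusted p = 0.000282), and SLAMF7, a leukocyte surface receptor (5.59 ± 1.10, adjusted p = 0.00433). FCGR2B and FCGR2C, which encode Fc gamma receptors of near-identical sequence whose reads can be split, also rose (5.59 ± 1.13 and 9.17 ± 1.66). F5, coagulation factor V, fell by 0.74 ± 0.17 (adjusted p = 0.0115), and DDR2, a collagen receptor, fell by 0.54 ± 0.10 (adjusted p = 0.00285). In simulated data for this comparison, 60% of 4-fold and 27.9% of 2-fold changes were called without the block, and 80% and 55.7% with it.

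A comparison added after the data were seen averaged co-culture against monoculture over vehicle and levofloxacin, with and without LPS, keeping the block. It called 401 genes, 221 higher and 180 lower, against 107 without the block (88 higher, 19 lower). The fit counts pairs of libraries of the same replicate number as independent. Such pairs can share differences, so its p-values may be too small. With the block, lower genes outnumbered higher ones with DESeq2 size factors (207 higher, 214 lower), the DESeq2 test (216 and 235) and no filter on low counts (158 and 170). Leaving out replicate 4 gave 198. FMO1, a flavin monooxygenase (-2.06 ± 0.36, adjusted p = 0.000156), and HSD3B2, a steroid dehydrogenase (-1.32 ± 0.28, adjusted p = 0.000997), fell with the block only (adjusted p = 0.109 and 0.428 without it). C1QA rose by 5.53 ± 0.55 (adjusted p = 1.41e-07) and C1QB by 4.93 ± 0.50 (adjusted p = 1.42e-07). These are among the genes with the largest changes under the size rule, applied to the blocked values after they were seen.

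LPS was then compared with no LPS. In co-culture with vehicle, IFI6, an interferon-induced gene, had the largest value among the named interferon genes, at a log2 fold change of 1.80 ± 0.70 (edgeR adjusted p = 1), higher in 3 of 3 pairs. The 6 tested genes of the interferon response list stood higher with LPS (camera adjusted p = 0.00299; adjusted p = 0.0122 with an estimated correlation, and 0.147 with both the block and an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The list lost its call without the library of replicate 3 without LPS (0.185) or of replicate 1 with LPS (0.105). Macrophage markers also stood higher (camera adjusted p = 0.0163; adjusted p = 0.415 with an estimated correlation), with CTSS at 1.67 ± 1.17, C1QA at 1.75 ± 1.54, C1QB at 1.69 ± 1.61 and FCER1G at 1.34 ± 1.14, each at adjusted p = 1 (C1QA higher in 3 of 3 pairs, the others in 2 of 3). By fry the macrophage list did not pass (adjusted p = 0.745). Its camera call was lost without the libraries of replicate 3 (0.541) or 4 (0.354) without LPS, and the list stood lower without that of replicate 1 with LPS (0.306). Without the co-culture LPS library of replicate 1 these values were -0.46, -0.52, -0.90 and -0.88, and IFI44L, another interferon-induced gene, went from 1.66 ± 1.76 to -1.37. Lists that stood lower with LPS were those of cytosolic ribosome (adjusted p = 0.0163), mitochondrial ribosome (0.0163), oxidative phosphorylation (0.0311), glycolysis (0.0497) and fatty acid oxidation genes (0.0497). In these lists 0 members passed over all genes, and adjusted over the list alone 1 fatty acid oxidation gene fell. With an estimated correlation their adjusted p were 0.325, 0.233, 0.325, 0.228 and 0.228, and with the block the last 3 had 0.0516, 0.0867 and 0.233. All 5 calls were lost without the library of replicate 3 without LPS (0.519 to 0.602) and without those of replicates 1 (0.163 to 0.697) and 4 (0.099 to 0.495) with LPS. Without that of replicate 1 without LPS all but the mitochondrial ribosome list lost them (0.0559 to 0.199), and without that of replicate 4 without LPS all but the cytosolic ribosome list did (0.0519 to 0.119). The fatty acid oxidation list did so without replicate 3 with LPS (0.0603).

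edgeR called 0 genes for LPS in co-culture (16 at an unadjusted p under 0.05) and 0 in monoculture (3 at an unadjusted p under 0.05), as did DESeq2 and the fits with the block. The difference of the LPS effect between co-culture and monoculture gave 0 genes by edgeR and DESeq2 (8 at an unadjusted p under 0.05). For that difference the interferon response list stood higher in co-culture (camera adjusted p = 0.0324; adjusted p = 0.0638 with an estimated correlation; lost without any 1 of 7 of the 12 libraries, with adjusted p up to 0.363), with IFI6 at 1.92 ± 0.97 and IFI44 at 2.02 ± 1.48, both at adjusted p = 1.

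With vehicle and levofloxacin averaged and the block kept, a comparison also added after the data were seen, LPS in co-culture called 7 genes. Here too pairs of libraries of the same replicate number are counted as independent, so the p-values may be too small. IFI6 rose by 1.77 ± 0.31 (adjusted p = 0.00959), and the calgranulin genes S100A12 and S100A8, made by myeloid cells, rose by 4.13 ± 0.84 (adjusted p = 0.0236) and 3.25 ± 0.73 (adjusted p = 0.0457). CTSK, a lysosomal protease, rose by 1.29 ± 0.29 (adjusted p = 0.0457). APOA2, an apolipoprotein of high-density lipoprotein, fell by 0.61 ± 0.13 (adjusted p = 0.0236), and LINC02772, an RNA of unknown role, was also lower. Without the block 0 genes were called (36 at an unadjusted p under 0.05); leaving out replicate 1, 3 or 4 gave 0, 1 and 13. In monoculture the same average gave 0 (20 at an unadjusted p under 0.05).

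**Figure D1:**
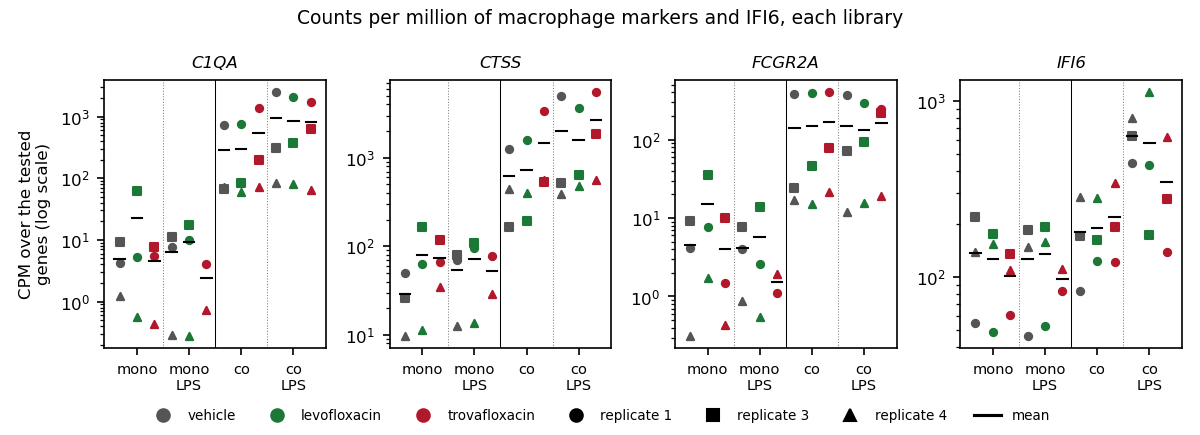
CPM (log axis) of C1QA, CTSS and FCGR2A, macrophage markers, and of IFI6 in each of the 35 libraries, by culture, LPS and drug, with marker shape for the replicate number and a bar for the group mean. C1QA lies between 59 and 2490 CPM in the co-culture libraries and at or under 17.4 CPM in monoculture, except for 61.7 CPM in the levofloxacin library of replicate 3 without LPS.

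Trovafloxacin was compared with vehicle in each of the 4 conditions. In monoculture without LPS, PHGDH (ENSG00000092621.13, chromosome 1, 119648411 to 119744226), which starts serine synthesis, fell by 2.95 ± 0.64 on the log2 scale (edgeR adjusted p = 0.00111), from a mean of 7538 to 976 CPM, and CTH, cystathionine gamma-lyase, fell by 1.58 ± 0.40 (adjusted p = 0.00374). FDPS, farnesyl diphosphate synthase of the cholesterol pathway, fell by 1.06 ± 0.11 (adjusted p = 2e-07). GADD45A (ENSG00000116717.13, 67685061 to 67688338), a growth arrest gene induced by DNA damage and stress, rose by 1.31 ± 0.21 (adjusted p = 4.55e-05), and MTF1, the metal-responsive transcription factor, by 1.36 ± 0.22 (adjusted p = 4.6e-05). CDC20, an activator of the anaphase-promoting complex, fell by 1.66 ± 0.42 (adjusted p = 0.00393), and LAMC1, a laminin chain, by 1.56 ± 0.34 (adjusted p = 0.00122). GSTM3, a glutathione transferase, fell by 1.02 ± 0.22 (adjusted p = 0.00122). Each of these moved one way in all 3 pairs of equal replicate number.

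Of the 16 genes that the size rule took, 8 rose and 8 fell. The rises included GRHL3 (4.20 ± 1.17), an epithelial transcription factor, NBPF13P, PTPN22, PRAMEF12, C1orf162, SPRR2G and CIART (2.5 ± 0.36, adjusted p = 1.01e-05), a circadian repressor. The falls were SH2D2A (-4.42 ± 0.94), NIBAN1, SLC6A17, COL11A1 (ENSG00000060718.22, 102876467 to 103108872; -4.13 ± 1.02) and COL8A2 (-3.98 ± 0.66), collagen chains, HSPB7, EXTL1 and MTCO3P12 (-3.37 ± 0.86). MTCO3P12 and NBPF13P have near-identical copies elsewhere in the genome, so their reads can be split. SPRR2G was not called without any 1 of 5 libraries (adjusted p of 0.0599, 0.138 and 0.076 without vehicle replicates 1, 3 and 4, and 0.156 and 0.0765 without trovafloxacin replicates 3 and 4), nor with no filter on low counts (0.0626). The calls of the other genes named here held without any 1 library, with folds moved by over 1.5 times for GRHL3 (5.55 without vehicle replicate 1), NBPF13P (4.57 without it), PRAMEF12 (4.74 without it, 2.73 without trovafloxacin replicate 1), SH2D2A (-5.39 without trovafloxacin replicate 4) and NIBAN1 (-3.48 without vehicle replicate 3). So did COL11A1 (-3.31) and HSPB7 (-2.73) without vehicle replicate 3, and HSPB7 (-5.10), EXTL1 (-4.55) and MTCO3P12 (-4.48) without trovafloxacin replicate 1.

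In the fixed lists for this condition, cholesterol synthesis genes stood lower (5 tested; 2 fell over all genes and 2 adjusted over the list alone; camera adjusted p = 0.0375, adjusted p = 0.425 with an estimated correlation), and 1 fell over all genes without vehicle replicate 1 or trovafloxacin replicate 3 or 4. The list lost its call without vehicle replicate 1 (0.128) or trovafloxacin replicate 4 (0.0744). Of 3 p53 target genes 2 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0862). They were GADD45A and PLK3 (0.87 ± 0.27, adjusted p = 0.0178), a stress kinase that lost its call without vehicle replicate 1 (0.0548) or 3 (0.0642) or trovafloxacin replicate 3 (0.0746). SESN2 stood at 0.64 ± 0.28 (adjusted p = 0.0951; 0.000176 with the block). Of 3 genes of the ATF4 stress list PHGDH and CTH fell and 0 rose, and adjusted over the list alone 2 fell and 1 rose (camera adjusted p = 0.527). MRPL37 (-0.59 ± 0.15, adjusted p = 0.00482) and MRPL24 (-0.79 ± 0.28, adjusted p = 0.0331), 2 of 3 mitochondrial ribosome genes over all genes and adjusted over the list alone, fell (camera adjusted p = 0.202), MRPL24 with its call lost without vehicle replicate 3 (0.198) or 4 (0.0781) or trovafloxacin replicate 1 (0.119) or 4 (0.0733). Without vehicle replicate 3, PHGDH fell by 2.32.

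Over all genes the edgeR test called 509, 278 higher and 231 lower, and 948 with the replicate block (484 higher, 464 lower). A fit on the groups compared only called 337 genes. APOA2 (1.63 ± 0.65, adjusted p = 0.0617), VCAM1, an adhesion molecule (-2.10 ± 1.36, 0.263), and NR0B2, a nuclear receptor (2.46 ± 1.28, 0.155), passed with the block only (2.08e-07, 0.000949 and 0.00138).

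With LPS in monoculture, trovafloxacin had 2 libraries (replicates 1 and 4) and vehicle 3 (replicates 1, 3 and 4). Values without the block can thus also hold the difference of replicate 3 from the other numbers. FDPS fell by 0.99 ± 0.13 (edgeR adjusted p = 4.53e-06) and COL8A2 fell by 4.33 ± 0.79 (adjusted p = 0.000363, and 6.22e-05 with the block). Both calls held without any 1 vehicle library. PHGDH fell by 2.79 ± 0.75 (adjusted p = 0.00935), and its call was lost without trovafloxacin replicate 1 (-2.58, adjusted p = 0.119) or 4 (-3.06, 0.0704). GADD45A rose by 0.91 ± 0.23 (adjusted p = 0.00632), with the call lost without trovafloxacin replicate 1 (0.65, adjusted p = 0.161). CTH fell by 1.5 ± 0.45 (adjusted p = 0.0215), with the call lost without vehicle replicate 3 (-1.06, adjusted p = 0.126) or trovafloxacin replicate 1 (-1.82, 0.0676) or 4 (-1.25, 0.207). PRAMEF12 (4.31 ± 0.96) and GRHL3 (4.02 ± 1.2) were among the largest rises, and NIBAN1 (-4.59 ± 1.07) and COL11A1 (-4.43 ± 1.24) were, with COL8A2, the largest falls. With the block the edgeR adjusted p was 2.25e-05 for PRAMEF12, 8.3e-05 for GRHL3, 5.39e-06 for NIBAN1 and 2.07e-06 for COL11A1. GRHL3 lost its call without vehicle replicate 3 (0.0739) or 4 (0.0712) or trovafloxacin replicate 1 (0.0917). NIBAN1 and COL11A1 did so without trovafloxacin replicate 1 (0.0599 and 0.147) or 4 (0.0578 and 0.0891). Without vehicle replicate 1 the log2 fold changes were 5.59 for PRAMEF12 and 5.44 for GRHL3, and without vehicle replicate 3 they were -3.68 for NIBAN1 and -3.53 for COL11A1.

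In the fixed lists, 1 of 5 cholesterol genes fell over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0788; 0.0376 with the block), and 1 of 3 p53 targets rose (1 adjusted over the list alone; 0.267). In the ATF4 list PHGDH and CTH fell (2 adjusted over the list alone; 0.403). With an estimated correlation the adjusted p of the cholesterol list was 0.713, and 0.186 with the block as well. The edgeR test called 341 genes, 193 higher and 148 lower, and 794 with the block (412 higher, 382 lower). Without trovafloxacin replicate 1 or 4 it called 163 and 150, and a fit on the groups compared only called 141.

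In co-culture without LPS, PHGDH fell by 2.61 ± 0.63 (edgeR adjusted p = 0.00311), CTH by 1.6 ± 0.40 (adjusted p = 0.00372) and FDPS by 0.92 ± 0.11 (adjusted p = 1.33e-06). GADD45A rose by 1.27 ± 0.21 (adjusted p = 6.12e-05). CSF1, the growth factor of macrophages, rose by 1.59 ± 0.44 (adjusted p = 0.00825), with the call lost without trovafloxacin replicate 4 (0.87, adjusted p = 0.137). LAMC1 fell by 1.41 ± 0.34 (adjusted p = 0.00307) and CDC20 by 1.69 ± 0.42 (adjusted p = 0.00368). Without vehicle replicate 3, PHGDH fell by 1.86. Each of these genes moved one way in 3 of 3 pairs. Macrophage markers averaged 2130, 295 and 175 CPM in the trovafloxacin libraries of replicates 1, 3 and 4 and 1040, 82.4 and 175 CPM in the vehicle libraries.

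The size rule took CIART (2.55 ± 0.35, adjusted p = 6.92e-06), OVGP1, an oviduct glycoprotein (2.47 ± 0.22, adjusted p = 5.01e-08), GRHL3, POU3F1, SPRR2G, PRAMEF12 and NHLH1 among the rises. The falls were COL11A1, SH2D2A, NIBAN1, SLC6A17, PADI1, a peptidylarginine deiminase (-3.56 ± 0.39, adjusted p = 5.06e-07), HSPB7, SLC6A9, a glycine transporter (-3.00 ± 0.50, adjusted p = 7.43e-05), and COL8A2. Log2 fold changes ran from 2.43 to 3.94 and from -3.99 to -2.93. Calls were lost without vehicle replicate 3 for GRHL3 (adjusted p = 0.0615), POU3F1 (0.0941), PRAMEF12 (0.067) and NHLH1 (0.054). They were lost without trovafloxacin replicate 3 for SPRR2G (0.103), NHLH1 (0.0693) and HSPB7 (0.0513). POU3F1 (0.0912 without vehicle replicate 4, 0.0574 without trovafloxacin replicate 1) and PRAMEF12 (0.0563 and 0.0603 without vehicle and trovafloxacin replicate 1) lost theirs in further fits. Folds moved by over 1.5 times with the call held for GRHL3 (4.69) and POU3F1 (4.68) without vehicle replicate 1, and for SPRR2G (3.64) without vehicle replicate 4. They did so for COL11A1 (-3.14), NIBAN1 (-2.86), SLC6A17 (-2.99) and HSPB7 (-2.77) without vehicle replicate 3, and for HSPB7 (-5.04) and COL8A2 (-3.69) without trovafloxacin replicate 1.

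In the fixed lists for this condition, 2 of 5 cholesterol genes fell over all genes and 3 adjusted over the list alone (camera adjusted p = 0.059), and 3 of 3 p53 targets rose (3 adjusted over the list alone; 0.059). PLK3 (0.84 ± 0.27, adjusted p = 0.023) lost its call without vehicle replicate 1 (0.0696) or 3 (0.0941) or trovafloxacin replicate 3 (0.0963) or 4 (0.0838). SESN2 (0.88 ± 0.28, adjusted p = 0.023) lost its call without vehicle replicate 1 (0.083) or 4 (0.0601) or trovafloxacin replicate 3 (0.251). In the ATF4 list PHGDH and CTH fell and SESN2 rose (2 and 1 adjusted over the list alone; 0.602), and MRPL37 and MRPL24, 2 of 3 mitochondrial ribosome genes, fell (2 adjusted over the list alone; 0.128). Without vehicle replicate 3 both lost their calls (0.0621 and 0.142), and MRPL24 did so without trovafloxacin replicate 3 (0.0546). Of 5 complement and coagulation genes 1 rose over all genes, and 3 rose and 1 fell adjusted over the list alone (0.619); the 1 call was lost without vehicle replicate 1 or 3 or trovafloxacin replicate 4. Of 3 fatty acid oxidation genes ACADM fell (-0.59 ± 0.20, adjusted p = 0.0333), and 1 rose and 1 fell adjusted over the list alone (0.945). ACADM lost its call without vehicle replicate 3 (0.276) or trovafloxacin replicate 3 (0.0622) or 4 (0.118), and with no filter on low counts (0.0594). The edgeR test called 496 genes, 271 higher and 225 lower, and 956 with the block (493 higher, 463 lower). Without trovafloxacin replicate 3 it called 320, and a fit on the groups compared only called 174. In simulated data for this comparison 64.5% of 4-fold and 28.1% of 2-fold changes were called without the block, and 91.9% and 57.9% with it.

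With LPS in co-culture, FDPS fell by 0.84 ± 0.11 (edgeR adjusted p = 2.91e-06), PHGDH by 2.61 ± 0.63 (adjusted p = 0.00317) and CTH by 1.71 ± 0.40 (adjusted p = 0.00229). GADD45A rose by 1.25 ± 0.21 (adjusted p = 6.95e-05) and CSF1 by 1.65 ± 0.44 (adjusted p = 0.00611). F5 fell by 1.41 ± 0.35 (adjusted p = 0.00375) and SLC2A1, a glucose transporter, by 0.56 ± 0.15 (adjusted p = 0.00559). APOA2 rose by 2.02 ± 0.66 (adjusted p = 0.0227), with the call lost without vehicle replicate 3 (1.69, adjusted p = 0.108) or trovafloxacin replicate 4 (1.5, 0.121). IFI6 stood at -0.85 ± 0.68 (adjusted p = 0.379; -1.04 ± 0.43 and 0.0432 with the block). Without vehicle replicate 3, PHGDH fell by 1.79. The macrophage marker list did not pass (8 tested, 0 called over all genes and 0 adjusted over the list alone, camera adjusted p = 0.836).

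Among the rises the size rule took CIART (2.52 ± 0.35, adjusted p = 8.43e-06), OVGP1 (2.57 ± 0.22, adjusted p = 2.3e-08), GRHL3, PRAMEF12, SPRR2G, MYOCOS and RPSAP18, a pseudogene whose reads can be shared. MYOCOS had 0 counts in the vehicle libraries and was at least 23.3-fold higher (floor of 3 counts over the group), but it lies opposite another gene and the strand setting of the counting is not known. The falls were SH2D2A, COL11A1, HSPB7, NIBAN1, SLC6A17, EXTL1, SYNC, an intermediate filament protein (-3.34 ± 0.44, adjusted p = 3.65e-06), and PADI1 (-3.26 ± 0.38, adjusted p = 9.35e-07). Calls were lost for GRHL3 without vehicle replicate 3 (0.0763) or 4 (0.0613), and for SLC6A17 without vehicle replicate 3 (0.058). They were lost for PRAMEF12 without trovafloxacin replicate 1 (0.0758), and for RPSAP18 without vehicle replicate 1 (0.0537) or trovafloxacin replicate 3 (0.0697). SPRR2G lost its call without vehicle replicate 1 (0.0527), 3 (0.0644) or 4 (0.0656) or trovafloxacin replicate 3 (0.111). Folds moved by over 1.5 times with the call held for GRHL3 (4.45) and PRAMEF12 (3.84) without vehicle replicate 1, for EXTL1 (-2.93) without vehicle replicate 4, and for SH2D2A (-5.58) and HSPB7 (-4.88) without trovafloxacin replicate 1. They did so for COL11A1 (-3.55), HSPB7 (-3.39) and NIBAN1 (-2.62) without vehicle replicate 3.

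In the fixed lists with LPS in co-culture, 3 of 5 cholesterol genes fell and 3 of 3 p53 targets rose, and as many adjusted over the list alone (camera adjusted p = 0.0584 for both lists). Without vehicle replicate 1 or trovafloxacin replicate 1, 3 or 4, 2 cholesterol genes fell. PLK3 lost its call without vehicle replicate 1 (0.175) or 3 (0.114) or trovafloxacin replicate 3 (0.133) or 4 (0.125), and SESN2 without vehicle replicate 1 (0.0749) or trovafloxacin replicate 3 (0.143). In the ATF4 list PHGDH and CTH fell and SESN2 rose (0.557), and MRPL37 and MRPL24, 2 of 3 mitochondrial ribosome genes (0.338), and SLC2A1, 1 of 3 glycolysis genes (0.381), fell, again as many adjusted over the list alone. MRPL37 and MRPL24 lost their calls without vehicle replicate 3 (0.207 and 0.321) or trovafloxacin replicate 3 (0.0517 and 0.0546). MRPL24 also did so without vehicle replicate 4 (0.0692) or trovafloxacin replicate 1 (0.0977) or 4 (0.104). Of 5 complement and coagulation genes 1 rose and 1 fell over all genes, and 2 rose and 1 fell adjusted over the list alone (0.557); the rise was lost without vehicle replicate 1 or 3 or trovafloxacin replicate 3. The edgeR test called 519 genes, 275 higher and 244 lower, and 956 with the block (484 higher, 472 lower). Without trovafloxacin replicate 3 it called 342, and a fit on the groups compared only called 214.

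**Figure D2:**
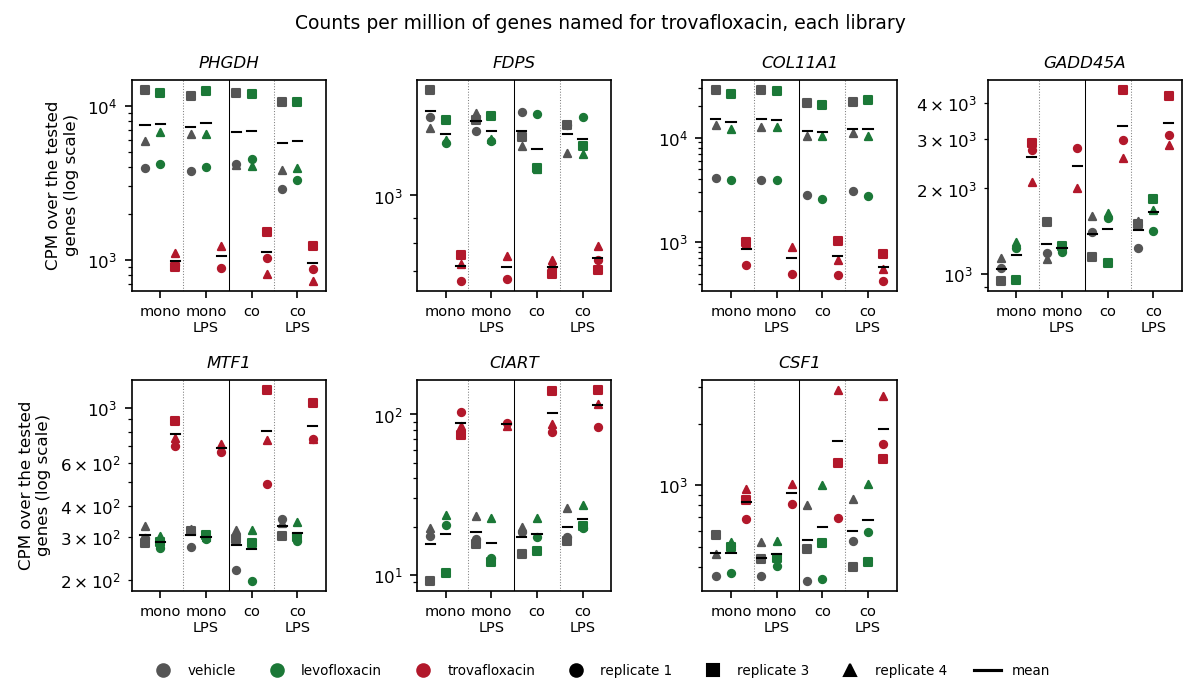
CPM (log axes) of 7 genes named for trovafloxacin in each library, by culture, LPS and drug, with marker shape for the replicate number and a bar for the group mean. PHGDH averaged 976 CPM with trovafloxacin and 7538 with vehicle in monoculture without LPS.

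Across the 4 conditions, which share replicate numbers but no libraries, 163 genes were higher and 124 lower with trovafloxacin in all of them, and 0 were higher in one and lower in another. Libraries of the same replicate number can share differences, so the conditions are not independent repeats. The count of genes higher in both of a pair of conditions lay between 172 and 237, and independent lists of those sizes would share between 28.7 and 42. For lower genes the counts were 132 to 194 against 18.3 to 31. Across genes, which are not independent replicates, the Pearson correlation of log2 fold changes lay between 0.83 and 0.908. The difference of the trovafloxacin effect between co-culture and monoculture called 0 genes by edgeR and DESeq2 without LPS (12 at an unadjusted p under 0.05) and 0 with LPS (13). The difference between LPS and no LPS in co-culture called 0 by both tools (5 at an unadjusted p under 0.05). In simulated data for the first of these differences, 40.8% of 4-fold and 11.1% of 2-fold changes were called without the block, and 56.3% and 43.1% with it. Each planted change was equal in all replicates, so these shares may be too high for the real data. With the block the real data also gave 0 genes for each of the 3 differences (44, 48 and 30 at an unadjusted p under 0.05).

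**Figure D3:**
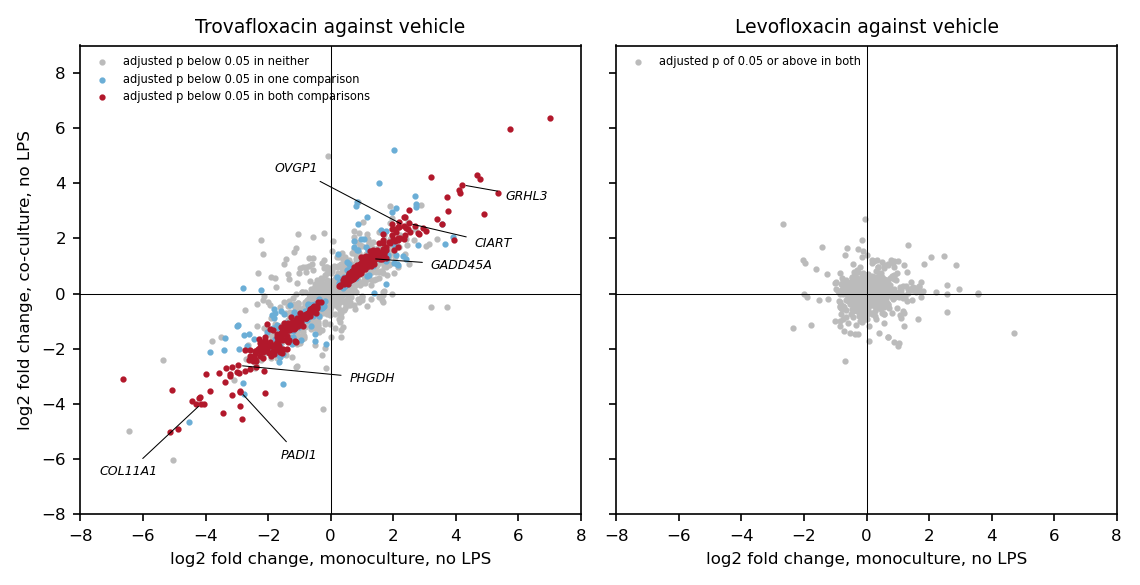
Log2 fold change against vehicle without LPS of each tested gene in monoculture (horizontal) and co-culture (vertical), for trovafloxacin (left) and levofloxacin (right), coloured by the edgeR adjusted p. For trovafloxacin 236 genes rose in both conditions and 183 fell in both, and for levofloxacin 0 genes passed in either.

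Levofloxacin, a fluoroquinolone like trovafloxacin, was the second compound, at the same concentration and time. edgeR called 0 genes against vehicle in each condition: monoculture (3 at an unadjusted p under 0.05), monoculture with LPS (8), co-culture (5) and co-culture with LPS (7), and DESeq2 and the blocked fits also called 0. At the genes called for trovafloxacin the median absolute log2 fold change of levofloxacin was 0.0719, 0.0548, 0.0586 and 0.0707 in these conditions, against 1.27, 1.25, 1.23 and 1.22 for trovafloxacin, which these genes were selected on. Over all 1821 genes it was 0.103, 0.0767, 0.0719 and 0.0993 for levofloxacin and 0.69, 0.674, 0.664 and 0.659 for trovafloxacin. With the block, both ends of the 95% interval of the levofloxacin effect were smaller in size than 0.5 times the trovafloxacin effect for 308 of 509, 235 of 341, 324 of 496 and 317 of 519 genes. The cholesterol list stood lower with levofloxacin in monoculture without LPS (5 tested, 0 called over all genes and 0 adjusted over the list alone, median log2 fold change -0.21; camera adjusted p = 0.00936, adjusted p = 0.483 with an estimated correlation and 0.0347 with the block as well). That call was lost without vehicle replicate 1 (0.595) or 3 (0.19) or levofloxacin replicate 1 (0.0551), 3 (0.356) or 4 (0.116). With the block alone the cholesterol list also passed in co-culture without LPS (0.0449, against 0.225 without). The macrophage list did so in monoculture without LPS (0.0107, against 0.211 without). There the macrophage markers averaged 32.4, 82.7 and 3.12 CPM in levofloxacin replicates 1, 3 and 4. In the vehicle replicates they averaged 23.4, 18.1 and 2.78 CPM, so the gap was widest in replicate 3. With the block and an estimated correlation neither of these calls held (camera adjusted p = 0.192 and 0.853).

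Trovafloxacin was compared with levofloxacin directly, to set a naphthyridone with a difluorophenyl group against the S-enantiomer of ofloxacin. In co-culture without LPS, PHGDH was lower with trovafloxacin by -2.62 ± 0.63 (edgeR adjusted p = 0.003), CTH by -1.68 ± 0.40 (0.00252) and FDPS by -0.81 ± 0.11 (6.96e-06). GADD45A was higher by 1.21 ± 0.21 (0.000104), CIART by 2.5 ± 0.35 (9.76e-06), OVGP1 by 2.61 ± 0.22 (1.71e-08) and PRAMEF12 by 3.30 ± 0.87 (0.00649). PADI1 was lower by -3.58 ± 0.40 (5.32e-07) and SLC6A9 by -2.99 ± 0.50 (7.85e-05). With LPS in co-culture PHGDH was lower by -2.65 ± 0.63 (0.00284), CTH by -1.82 ± 0.40 (0.0014) and FDPS by -0.81 ± 0.11 (5.72e-06), and GADD45A was higher by 1.04 ± 0.21 (0.000581). SYNC was lower by -3.2 ± 0.44 (6.95e-06). Without levofloxacin replicate 3, PHGDH was lower by -1.92 without LPS and -1.89 with LPS.

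The direct comparison called 526 genes in monoculture (981 with the block), 346 in monoculture with LPS (789), 485 in co-culture (971) and 531 in co-culture with LPS (961). In monoculture with LPS 147 and 152 were called without trovafloxacin replicates 1 and 4, and 223 without levofloxacin replicate 3. In co-culture 310 were called without trovafloxacin replicate 3, and with LPS 341 without it. A fit on the groups compared only called 134 in monoculture with LPS, 95 in co-culture and 218 in co-culture with LPS. In monoculture NBPF13P was higher by 4.32 ± 0.69 (edgeR adjusted p = 4.16e-05). With LPS PRAMEF12 was higher by 5.09 ± 1.02 (0.000988, and 8.59e-06 with the block), and COL8A2 was lower by -4.20 ± 0.79 (0.000516, and 7.47e-05 with the block). Replicate 3 was absent from the trovafloxacin group with LPS in monoculture. Cholesterol genes fell by this comparison for 2 of 5 in co-culture without LPS and 3 of 5 with LPS, and as many adjusted over the list alone (camera adjusted p = 0.137 and 0.0933). With LPS 2 fell without trovafloxacin replicate 1, 3 or 4 or levofloxacin replicate 1.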

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

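The interferon response list differed between culture formats in its response to LPS: the LPS effect was higher in co-culture than in monoculture (6 tested genes, 5 with a positive difference, median 0.80 on the log2 scale, camera adjusted p = 0.0324). The adjusted p was 0.0638 with an estimated correlation, 0.0146 with the replicate block and 0.268 with both, and 0.911 by fry. Macrophage markers averaged 2790, 289 and 151 CPM in the co-culture vehicle libraries of replicates 1, 3 and 4 with LPS, and 1040, 82.4 and 175 CPM without it. Among the interferon genes, the log2 fold change of IFI44L with LPS in co-culture was 1.66, and -1.37 without the LPS library of replicate 1. In fits without 1 library, a test chosen after the data were seen, the adjusted p of the list was 0.0145 to 0.363. Of the 12 libraries, 7 ended the call: co-culture replicate 1 with LPS (0.363) and 3 without (0.318), and monoculture replicates 1 (0.0846) and 3 (0.182) with LPS and 1 (0.0571), 3 (0.0724) and 4 (0.0976) without. No explanation was tested for this list.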

How the results depend on the processing

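The replicate block, DESeq2, the filter, the groups-only fit and leaving out single libraries were planned; leaving out whole replicate numbers, leaving out single libraries in the list tests and all settings of the averaged comparisons were chosen after seeing the data. With the replicate block the counts were 48 for culture, 948, 794, 956 and 956 for trovafloxacin against vehicle (monoculture, monoculture with LPS, co-culture, co-culture with LPS) and 981, 789, 971 and 961 against levofloxacin. For culture with the block, leaving out 1 library gave from 5 to 52. Without the block the averaged comparisons gave 0 for LPS in co-culture and 107 for culture. DESeq2 called 21 genes for culture, and with the block 1 for the averaged difference of the LPS effect. The fit on the groups compared only gave 337, 141, 174 and 214 for trovafloxacin against vehicle and 134, 95 and 218 against levofloxacin in monoculture with LPS, co-culture and co-culture with LPS. Of the list tests 11 passed, against 1 with an estimated correlation and 27 by fry. All 27 were in comparisons of trovafloxacin with vehicle or levofloxacin, and fry ended 10 of the 11 camera calls. The cause was not tested.

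Leaving out 1 library or 1 replicate number gave from 162 to 517, 27 to 392, 161 to 478 and 141 to 500 genes for trovafloxacin against vehicle in the order above, and from 156 to 506, 23 to 377, 155 to 478 and 129 to 515 against levofloxacin. The lowest values came without replicate 4, and why was not tested. Named genes lost calls in these fits as well: 44 of their values did so without replicate 3. Most of their called values did so without replicate 4, where trovafloxacin with LPS in monoculture kept 1 library. For the averages the range was 0 to 13 for LPS in co-culture, 0 to 1 for the difference and 198 to 460 for culture. For LPS in co-culture, leaving out 1 vehicle library gave from -0.46 to 2.73 for CTSS, -0.88 to 2.71 for FCER1G, -0.52 to 3.83 for C1QA, -0.90 to 3.80 for C1QB and -1.37 to 4.72 for IFI44L, the lowest without the LPS library of replicate 1. Without that library the macrophage list stood lower with LPS (camera adjusted p = 0.306), and over all such fits its adjusted p ran from 4.11e-08 to 0.541. Of 166 called values of named genes 105 were called in every fit without 1 library, 75 moved by over 1.5 times in at least 1, and 0 turned direction. Among 204 results compared, called or not, the groups-only fit ended 46 calls. Among 208 such results, no filter on low counts ended 11 calls and the DESeq2 test 1. Among 251 results compared, called or not, the block ended 3 calls, those of the glycolysis, oxidative phosphorylation and fatty acid oxidation lists with LPS in co-culture, and 16 results passed only with it. With DESeq2 size factors all 208 results compared kept their direction and side of the threshold.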

Other observations

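The tests in this part were chosen after the data were seen, apart from the splits of the comparisons that are not averages. Genes were grouped by symbol root into 53 families, and the collagen family (5 tested) stood lower with trovafloxacin in all 4 conditions (camera adjusted p = 0.00155 in monoculture, 0.00134 with LPS, 0.00355 in co-culture and 0.00487 with LPS; adjusted p = 0.0179, 0.0165, 0.0288 and 0.0347 with an estimated correlation). A list of extracellular matrix genes written after that (20 tested) had 10, 10, 9 and 9 lower genes and 0 higher in these conditions, with a median log2 fold change from -1.53 to -1.42 (blocked camera p with an estimated correlation from 0.000241 to 0.000349). A list of splicing factors (28 tested) had 20, 15, 20 and 21 higher genes and 1, 0, 1 and 0 lower, with medians from 0.68 to 0.86 (blocked camera p with an estimated correlation from 0.0806 to 0.0976). Both lists were picked on these libraries, so their counts are not independent evidence of a direction.

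Genes spanning over 200 kb (86 tested) stood lower with trovafloxacin, with blocked median log2 fold changes from -0.57 to -0.40 against 0.03 to 0.09 for other genes. Against shorter genes matched on exonic length, GC content and level, the difference nearest to 0 was -0.464 (95% bootstrap interval -0.805 to -0.292), which argues against those properties as the whole cause in these libraries. The bootstrap resampled genes, which are not independent, so its interval does not measure the spread between libraries. A loss graded with span stays open: the partial Spearman correlation across genes nearest to 0 was -0.113, and -0.0969 among genes up to 200 kb, a check added after the first, but binned medians up to 200 kb stayed between -0.06 and 0.15. Loss of mesenchymal cells cannot be told apart from these, since 0 mesenchymal markers were tested. An effect of the drug on long transcripts may therefore be put forward only as a hypothesis.

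Of 5 chromosome 1 copies of mitochondrial genes, 4 were lower with trovafloxacin with the block in all 4 conditions, as MTATP6P1 (-2.00 ± 0.13, blocked, monoculture without LPS). These 4 match a mitochondrial transcript at 98% identity or more, so reads shared with mitochondrial transcripts could account for the fall. MTND2P28, at 98.4% identity, had -0.51 ± 0.17 there and -0.13 ± 0.17 in co-culture with LPS. The other tested pseudogenes had a lowest median of 0.107, which argues against a general fall of pseudogene counts.

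Macrophage transcripts in the co-culture fraction varied together: the first component of 8 markers over 18 libraries held 94.7% of their variance, against a median of 51.2% and a 95th percentile of 67.1% in 1000 random sets of matched level. Kupffer cells carried past the CD163 beads may be the source, and RNA set free by them was not tested apart. With vehicle and levofloxacin averaged within each of 3 replicate numbers, the mean log2 difference with LPS ran from 0.28 ± 0.88 (SD) for FCGR2A to 1.39 ± 0.94 for C1QA. The order of the 8 markers was shared between the numbers (Kendall's W = 0.815, permutation p = 0.00111, and at most 0.0128 without any 1 marker). A larger carried-over share alone predicts equal differences only where the markers have no other signal. In monoculture with vehicle and no LPS, replicate 1 averaged 23.4 CPM over the 8 markers and 4.2 CPM for C1QA. Such signal was thus uneven between markers and could give a shared order too. The order therefore does not decide whether a larger carried-over share is the whole cause of the higher markers with LPS.

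Splits of the libraries were compared with the real groups. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Trovafloxacin against vehicle called 509, 496 and 519 genes in the conditions with 3 libraries, and against levofloxacin 526, 485 and 531, with 0 in any other split, so 1 split of 10 was as large. For co-culture, LPS and levofloxacin against vehicle, the real split and the highest other gave 0, so 10 of 10 splits were as large. With the block, the real split for co-culture called 48 genes and the other 3 splits that part all 3 pairs called 0, and for LPS and levofloxacin both gave 0. For the differences of the LPS effect, and of the trovafloxacin effect by culture and by LPS, 100 of 100 regroupings gave as many as the real 0, as any count would, so these shares decide nothing. The highest of the others gave 20, 838 and 549. The regroupings with 838 and 549 set 6 and 5 of the 6 trovafloxacin libraries on one side of the difference, and those with 3 on each side gave at most 5 and 27, so the high counts followed the structure of the samples by drug. For the 20 the cause was not tested. The pairs of libraries behind the averages belong to 3 replicate numbers, so the labels were swapped for whole numbers, which gives 4 regroupings, too few for a share under 0.05. With the block, 1 of 4 gave as many as the 7 genes for LPS in co-culture (highest other 0) and 1 of 4 as many as the 401 for culture (highest other 16). For LPS in monoculture and for the difference of the LPS effect, 4 of 4 gave as many as the real 0 (highest other 0).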
